A study of Mus musculus with 8 samples.

How the data were processed

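Gene and non-coding RNA expression was measured in gastrocnemius muscle, a muscle of the calf, in 8 samples from male mice of 10 weeks of age. Of these, 4 came from animals whose right sciatic nerve had been severed 7 days before and 4 from animals with an intact nerve, per the labels' protocols. Total RNA was copied into Cy3-labelled cRNA and hybridised to a 1-colour Agilent array made for mouse long non-coding RNAs, design 049801, per the labels and the file headers. The labels do not say which mouse each sample came from, so p-values measure the spread between these 8 samples.

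The deposited scanner tables hold linear spot intensity values, made by the authors with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. In the processed intensity used here, a fitted spatial background surface had been subtracted, a multiplicative trend removed and low values replaced by surrogates, with the global background adjustment off, per the file headers. The mean and local background intensities, also from the authors' scanner tables, carry no correction, per the file headers. Other columns used here are flags per spot that the authors' software set (well above background, saturated, outlier), per the file headers. Any scaling between arrays by the authors is not given in the sources used here.

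The authors' deposited value table holds log2 values for 7249 probes, and every row name matched a probe name on the arrays. Each of its columns correlated with the log2 processed intensity of the same array at 0.9998 or more across probes, so the scale is log2 and genes were not centred. Its values lay a median of 0.0017 from log2 intensities quantile-normalized here, with no centring. From values scaled on the 75th percentile they lay a median of 0.046, after each set was centred on its own overall mean. Column medians in the authors' deposited table were 5.59, 5.67, 5.57 and 5.75 for controls 1 to 4, and 6.33, 6.28, 6.41 and 6.36 for denervated samples 1, 5, 6 and 7. The smallest group difference in that table was 1.00 on the log2 scale and the largest unadjusted equal-variance p was 0.0499, so it holds preselected probes. Among all quantile-normalized probes 8390 met both criteria, of which 7184 were in the table; how the rest were left out is not given in the sources used here.

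Each array held 148260 spots, of which 143286 were not controls. These carried 91188 probes, 39410 with 1 spot, 51738 with 2 spots and 40 with 10 spots. No spot was saturated on any array, control spots included. Between 38 and 158 spots per array were marked as outliers and left out. Log2 processed intensities were averaged over the spots of a probe, and each array's 75th percentile over non-control probes was subtracted. A probe was tested when it was well above background, in a share of at least 0.5 of its spots, on all 4 arrays of at least 1 group. This left 52836 probes. Denervated and control arrays were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested probes and a threshold of adjusted p under 0.05. Measures with 1 value per array were compared with two-sided exact permutation tests, whose smallest possible p with 4 against 4 is 0.0286. They were adjusted over the 7 measures tested. A measure at that smallest p passes after adjustment only if several others reach it too. Failing to pass therefore does not argue against a difference. Where all arrays of a group were not well above background, the fold is a lower bound. It sets the mean of the brighter group against, on each dim array, the higher of the probe's own signal and the lowest signal among probes well above background.

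The fit was tested on simulated data for denervated against control over 52708 probes. It recovered 64% of 100 probes changed by 2-fold and 96% of 100 probes changed by 4-fold, and 6 of its 166 calls were false. Only these probes were changed, with noise drawn independently for each probe and array and no slide effect. In the data 53.2% of tested probes passed the threshold. The simulated recovery and false calls therefore do not measure those of the real comparison. For arrays, the number of samples limits the precision. The median standard deviation of a tested probe was 0.22 (log2) between control samples and 0.16 between denervated samples. Between 2 spots of a probe on the same array it was 0.13, over 27342 probes, which had 0.22 and 0.16 between samples. The median of an SD from 2 values understates the spread more than that of an SD from 4 values. How much of the spread between samples is spot noise can therefore not be read from these numbers.

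The files do not pair probe IDs with genes, and none of the reference tables used here lists these IDs. The counts of coding and non-coding genes, the 33 gene lists and cell type marker lists, and the genes to be named, all fixed before the data were examined, could therefore not be run. The probes named below follow the same rule of size, applied to IDs: the largest rises and falls past the threshold whose groups do not overlap. The limit to probes well above background on all 8 arrays, and to 2 rises and 2 falls, was set after the data were seen. Gapdh and Pgk1 could be named because 4 control probes carry these names in the files; each has 10 spots per array. They were fitted with the tested probes, adjusted over these 4, and chosen after the data were seen.

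All 4 control arrays lay on 1 slide and all 4 denervated arrays on another, and scans followed the slides, so slide or scan batch and group cannot be told apart. Alternatives fixed beforehand were normexp background correction with an offset of 50, quantile normalization, a percentile over probes detected on all arrays, other filters on dim probes, a floor, trended and robust moderation, array weights, outlier spots kept, the value table, a stricter threshold of 0.01 and each array left out in turn. Scaling on 8 probes for E1A, a viral RNA that serves as a spike-in on Agilent arrays, was added after the data were seen, with and without control 3.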

Results

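The series measured how gastrocnemius RNA differs 7 days after the sciatic nerve, which supplies this calf muscle, has been cut. It held 4 control and 4 denervated samples, each on 1 array. Between 51650 and 55429 of 91188 probes were well above background on the control arrays, and between 54545 and 57633 on the denervated arrays. The mean numbers were 53118 ± 1644 (SD, n = 4) and 55912 ± 1367 (SD, n = 4), a difference that did not pass the exact permutation test (p = 0.0857, adjusted p = 0.15).

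Transcripts of Gapdh and Pgk1, which encode enzymes of glycolysis, were lower in denervated than in control muscle relative to each array's 75th percentile. On probe Mouse-PGK1_5, Pgk1 fell by 1.74 on the log2 scale (SE 0.15), from 5.59 ± 0.28 to 3.85 ± 0.12 above the array's 75th percentile (SD, n = 4 each, limma adjusted p = 2.55e-06). The second Pgk1 probe, Mouse-PGK1_3, fell by 1.30 (SE 0.15, limma adjusted p = 2.15e-05). Gapdh fell by 0.84 on both of its probes, Mouse-GAPDH_5 (SE 0.16, limma adjusted p = 0.000802) and Mouse-GAPDH_3 (SE 0.34, limma adjusted p = 0.0338). In fold terms Pgk1 was 3.34-fold and 2.46-fold lower, and Gapdh 1.79-fold and 1.80-fold lower, on the probes ending in 5 and 3.

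All 4 denervated values lay below all 4 control values for both Pgk1 probes and for Mouse-GAPDH_5, but not for Mouse-GAPDH_3, where control 3 read 7.99 and the other controls between 9.44 and 9.78. The Mouse-GAPDH_3 call was lost when any 1 array other than control 3 was left out, with adjusted p up to 0.0959, and was at 4.99e-06 without control 3. With E1A spike-in scaling, Pgk1 fell by 1.11 and 0.67 (limma adjusted p = 0.00258 and 0.0422), while the Gapdh differences were -0.21 and -0.22 (limma adjusted p = 0.592 for both). Without control 3, spike-in scaling gave Gapdh differences of -0.54 and -0.78 (limma adjusted p = 0.00231 and 0.000295). With quantile normalization the Gapdh differences were -0.21 and -0.51 (limma adjusted p = 0.0916 for both), and no setting turned the direction of any of these 4 probes. Mouse Gapdh has many processed pseudogenes, whose transcripts such probes could also bind.

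The changes of both Pgk1 probes differed by 0.44 (SE 0.06, n = 4 each) with no overlap between the groups, which did not pass the threshold after adjustment (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0667). For Gapdh the corresponding difference was -0.01 (SE 0.24, n = 4 each, exact permutation p = 1). That value rested on control 3, where Mouse-GAPDH_3 minus Mouse-GAPDH_5 was -2.53. On the other controls it was -1.71 to -1.47, and on the denervated arrays -1.90 to -1.79. With control 3 set aside the groups did not overlap, in the direction opposite to Pgk1. The files do not say what the 3 and 5 in these probe names stand for. A further 7 control probes named for human or rat GAPDH and PGK1 also read lower in denervated muscle, by -0.76 to -1.89 on the log2 scale, and by -0.13 to -1.26 with E1A spike-in scaling. After scaling on the 75th percentile, all 29 other control probes well above background on every array, which include the E1A spike-ins, were lower too, by -0.35 to -0.98. Both mouse Gapdh changes of -0.84 lay inside that range but near its far end, where only DCP_1_4 (-0.85) and DCP_1_7 (-0.98) fell further. Both mouse Pgk1 changes lay beyond the range. So did Human-GAPDH_5 (-1.41), Rat-GAPDH_3 (-1.53) and Rat-GAPDH_5 (-1.10), while Human-GAPDH_3 (-0.76) lay inside it.

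**Figure D1:**
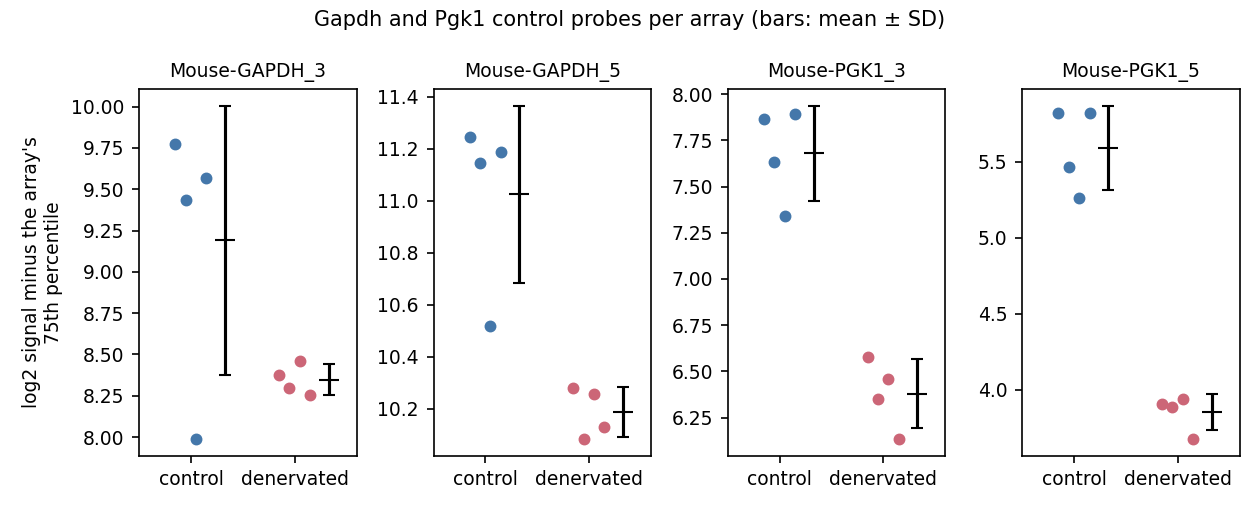
Log2 signal of the 4 Gapdh and Pgk1 control probes on each array, minus the array's 75th percentile (vertical axes, a separate range for each probe), for 4 control and 4 denervated samples; points are arrays and bars the mean ± SD. Pgk1 lay lower on every denervated array on both probes, and the low control point on both Gapdh probes is control 3.

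Across the array, 28098 of 52836 tested probes (53.2%) passed the threshold between denervated and control muscle (limma). Relative to each array's 75th percentile, 12111 were higher in denervated muscle and 15987 lower. At least 2-fold changes were more often rises, with 4667 higher and 2420 lower among 7087 probes. The values of the 2 groups did not overlap for 26036 tested probes (49.3%), where chance gives 2.86%. At an unadjusted p under 0.05 there were 31668 probes.

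The balance of higher and lower calls depended on the background correction, the scaling, the filter on dim probes and the threshold. Without a filter on dim probes, 29.1% of calls were higher in denervated muscle. Of all calls, 43.1% were higher with the 75th percentile, 32.3% with normexp background correction and 94.5% with E1A spike-in scaling. At a stricter adjusted p under 0.01, 51.1% were higher (8911 higher and 8543 lower). Among calls of at least 2-fold the shares were 65.9%, 79.6% and 94.7%, and 54.9% with the percentile taken over probes detected on all arrays. The median change of all tested probes was -0.14 on the log2 scale with the 75th percentile, -0.24 with the percentile over detected probes and 0.49 with spike-in scaling. All 12111 higher calls were also higher past the threshold with spike-in scaling. Of the 15987 lower calls, 1257 were also lower with spike-in scaling and 14730 did not pass the threshold there. Spike-in scaling raised the changes of all probes by about the same amount, so rises gained size and falls lost it by construction. These counts therefore do not test the rises or the falls. The 75th percentile itself was 6.51 ± 0.12 (log2, SD, n = 4) on control and 6.97 ± 0.08 on denervated arrays (exact permutation p = 0.0286, adjusted p = 0.0667).

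The probes with the largest changes measured on all 8 arrays moved by over 5 log2 units with the 75th percentile scaling. A_55_P2035424 rose by 6.63 (SE 0.45, limma adjusted p = 1.11e-05), from -2.17 ± 0.85 to 4.46 ± 0.71 (SD, n = 4 each). A_52_P413395 rose by 6.43 (SE 0.82, limma adjusted p = 0.000258), with a wide spread between controls (0.09 ± 2.01) and a narrow one between denervated samples (6.52 ± 0.23). A_55_P1994339 fell by 6.20 (SE 0.51, limma adjusted p = 2.59e-05) and A_55_P2067200 fell by 5.37 (SE 0.29, limma adjusted p = 4.45e-06). All 4 probes kept their direction and passed the threshold in each of 22 other settings. They had been picked for their size on these same arrays, which every setting reused in whole or in part. The authors' deposited table also holds only preselected probes. That all 4 passed was therefore largely set in advance. The sizes of the 4 changes varied between settings. With normexp background correction the changes were 4.84, 5.83, -4.27 and -4.67 in the order named, and spike-in scaling gave 7.25, 7.06, -5.57 and -4.74. The change of A_52_P413395 was 5.59 without control 1 and 7.21 without control 4. The files do not pair these IDs with genes.

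Some transcripts were well above background in only 1 of the groups. On all 4 denervated and no control arrays this held for 815 probes, of which 698 passed the threshold. Of those 698, 144 were at least 4-fold higher in denervated muscle, and the largest bound was at least 150-fold. The opposite held for 156 probes, of which 154 passed the threshold and, among these, 69 were at least 4-fold lower, with a largest bound of at least 22.3-fold. Among called probes with a positive log2 bound, the median bound was 2.35-fold higher and 3.69-fold lower. With control 4 set aside, 1340 probes were well above background on all denervated and no other control arrays. Detection was set on unscaled signals, and the denervated arrays were brighter (75th percentile 6.97 against 6.51, log2). How far brightness adds to the 815 was not tested.

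Relative to each array's 75th percentile, probes whose IDs start with A_51_P, A_52_P or A_65_P were more often higher than lower in denervated muscle, and those starting with mmu_ or A_30_P more often lower, which turned with E1A spike-in scaling and among changes of at least 2-fold. Of 5048 tested A_51_P probes 1849 were higher and 1022 lower, and of 3425 A_52_P probes 1345 were higher and 631 lower. Of 18219 mmu_ probes 2709 were higher and 6348 lower, and of 9132 A_30_P probes 1390 were higher and 3448 lower. Of the changes of at least 2-fold, 1011 mmu_ probes were higher and 888 lower, and 562 A_30_P probes were higher and 366 lower. Among 15631 A_55_P probes the numbers were close, 4377 and 4162. The median change of mmu_ and A_30_P probes lay below that of A_51_P and A_52_P probes by -0.42 on the log2 scale, and by -0.46 to -0.26 in 16 other settings of the scanner values. It was -0.10 in the authors' deposited table, which holds only preselected probes. With E1A spike-in scaling the mmu_ and A_30_P medians were 0.41 and 0.38, against -0.22 and -0.25 with the 75th percentile. The files do not say which of these IDs stand for coding and which for non-coding transcripts.

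**Figure D2:**
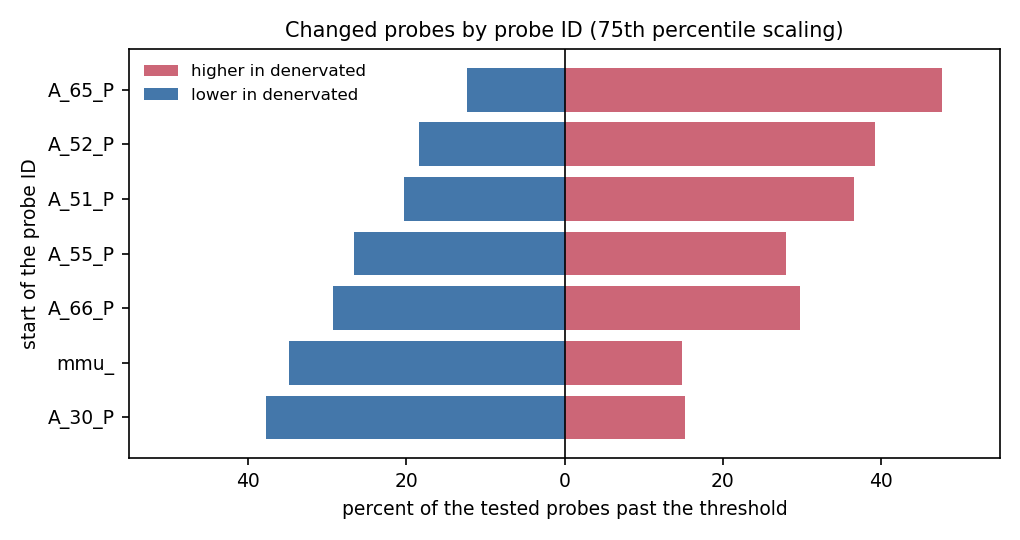
Share of tested probes past the threshold that were higher (right) or lower (left) in denervated muscle, in percent, by the start of the probe ID, after scaling on the 75th percentile. The share lower ran from 12.4% for A_65_P to 37.8% for A_30_P; with E1A spike-in scaling most calls of every kind of ID were higher.

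Denervated samples resembled each other more than controls did. Pearson correlations across tested probes, which are not independent replicates, were 0.991 to 0.993 between denervated arrays, 0.971 to 0.987 between control arrays and 0.928 to 0.958 between the groups. The first principal component held 71.2% of the variance and separated the groups. Because each group lay on a slide of its own, slide and denervation cannot be told apart in any of these comparisons.

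**Figure D3:**
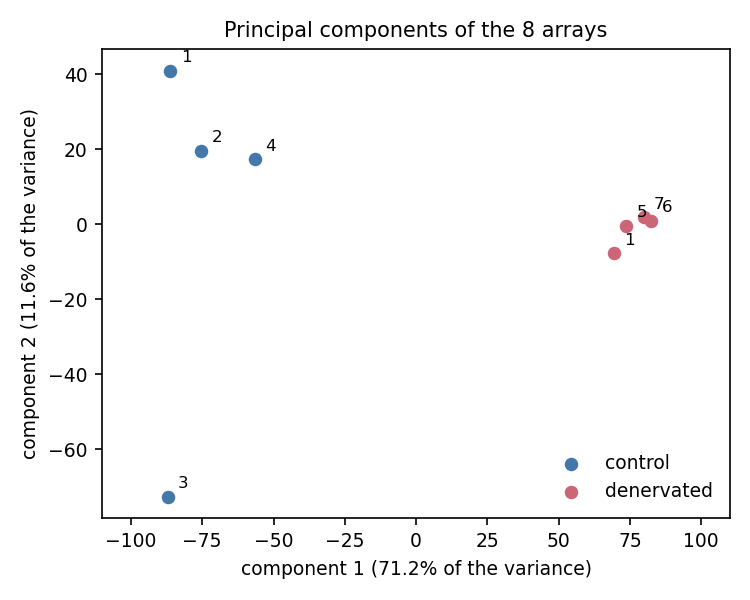
First and second principal components of the 8 arrays over tested probes well above background on all 8 arrays, with the share of variance on each axis. Points are arrays, numbered by replicate and coloured by group. Component 1 separates denervated from control arrays, control 3 lies apart on component 2 (-72.6), and control 4 (-56.5) is the control nearest the denervated arrays on component 1.

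Of the 7249 probes in the authors' deposited table, 5037 were higher and 2212 lower in denervated muscle. The fit here tested 6764 of them, of which 6759 passed the threshold and 6764 had the same direction. Both rest on the same arrays and the deposited table holds preselected probes, so this overlap was largely set in advance.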

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

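The test of slide effects was chosen only after the results were seen.

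In a screen of 38 groups of values for a sample far from the others, 2 stood out, both in control 3; chance marks about 1 group in 20. The mean E1A spike-in signal of control 3 was 8.69 (log2, before scaling), against 8.19 to 8.22 on the other control arrays. Its Mouse-GAPDH_5 value was 10.52, against 11.15 to 11.25 on the other controls. Control 3 also lay apart on the second principal component, at -72.6 against 17.4 to 40.9 for the other controls.

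The real grouping was the only 1 of 35 splits of the 8 arrays to reach 28098 probes past the threshold, which argues against a chance split. A share of 1 in 35 is the smallest that such a test can give. Each of the other 34 splits gave 0 in limma, with at most 5793 probes at an unadjusted p under 0.05. Those splits mix denervated and control arrays, so the group difference widens their spread. Their low counts were therefore likely in advance and do not measure chance. Slide effects that differ from probe to probe stay open and cannot be told apart from denervation, since 0 slides held arrays of both groups. The muscle's response to the loss of its nerve is the biological candidate, and the design leaves it beside the slide.

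Control 4 was shifted toward the denervated arrays: of 1340 probes well above background on all denervated and none of the other control arrays, 525 (39.2%) were well above background on control 4, while the like share for the other controls, each set against the rest, was 7.60% to 16.2%. Over changed probes well above background on all 8 arrays, the slope of control 4 on the denervated change was 0.19 after quantile normalization. The other controls ranged from -0.03 to 0.04, which argues against greater brightness of the array as the cause of this slope. The detection share rests on unscaled signals, which that slope cannot test. Control 4 was the brightest control (75th percentile 6.67 against 6.40 to 6.51, log2), so brightness stays open for that share. A uniform admixture of RNA like that of the denervated samples should give 1 share in every set of changed probes. In control 4 the implied share was 3.07% from probes risen at least 8-fold and 10.0% from those risen 2-fold to 4-fold. From probes fallen at least 2-fold it was 24.6%, so that the largest was 8.03 times the smallest. Control 3 gave 28.7% in the fallen probes, but -0.0012% and -1.70% in the same risen sets. The fallen set, and with it the 8.03, therefore cannot bear on admixture. Between the risen sets of control 4 the ratio was 3.27. The gap between them was 6.96 points for control 4 and at most 2.61 for the other controls, which argues against a uniform admixture. A state of that mouse or its muscle may lie behind the shift, but no biological explanation was tested, as the labels give only its group; leaving control 4 out gave 27688 probes past the threshold.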

How the results depend on the processing

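E1A spike-in scaling, with or without control 3, was chosen only after the results were seen. Of 22 other settings, 8 changed nothing but the arrays used, each leaving out 1. Those gave 23314 to 28301 probes past the threshold (10669 to 12136 higher, 12638 to 16165 lower) and 6850 to 7881 of at least 2-fold. The 2 named rises, 2 named falls and both Pgk1 probes kept direction and call in every setting that gave them a value. For the named rises and falls, picked for their size on these same arrays, this was largely set in advance. The Mouse-GAPDH_5 call was lost with quantile normalization and with spike-in scaling of all arrays, and the Mouse-GAPDH_3 call in 11 of 21 settings (adjusted p up to 0.592). Normexp left 3129 probes of at least 2-fold, 2490 higher and 639 lower; its offset of 50 shrinks folds of dim probes by construction. Without a filter on dim probes 91188 were tested and 42664 passed, 30236 lower, with 4239 at least 2-fold lower; the medians of A_51_P and A_52_P probes turned to -0.0606 and -0.0607. At adjusted p under 0.01, 17454 passed, 8911 higher and 8543 lower, so that the majority turned. In the authors' deposited table, which holds preselected probes, 7249 passed, 5037 higher and 2212 lower, and the medians of A_30_P, A_55_P, A_66_P and mmu_ probes were 1.19, 1.18, 1.24 and 1.14. With spike-in scaling 21481 probes were higher and 1258 lower, and 13895 at least 2-fold, 13158 higher and 737 lower; the same medians were 0.38, 0.55, 0.54 and 0.41. With control 3 left out as well these became 20894, 2739, 11200, 10126 and 1074, and 0.21, 0.39, 0.37 and 0.25. Which of the scalings is nearer the truth was not tested. Negative control probes differed by -0.01 between the groups before scaling, while the subtracted 75th percentile was 0.46 higher on denervated arrays. A probe at background therefore reads lower after scaling by construction. The lower calls and medians without a filter include such probes. How far the scaling accounts for the turned medians was not tested. No paired analysis was possible because the groups share only 1 replicate number. The slide as a block was not run, since slide and group coincide. The mean over probes of a gene, both other gene list tests and all gene counts were not run, since IDs are not paired with genes. Signal over background limited the tests to 52836 of 91188 probes.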

Other observations

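The comparison of kinds of probe ID, its test within deciles and the spike-in measures were chosen only after the data were seen.

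Relative to A_51_P and A_52_P probes, mmu_ and A_30_P probes read lower in denervated muscle, and the control medians of these kinds of ID ran from -1.08 (mmu_) to 0.16 (A_51_P), so dim signals could contribute to the pattern. Within deciles of the mean signal, however, the difference of medians was -0.36 (weighted over deciles, from -0.61 to -0.07 in single ones), which argues against dim signal as the whole cause. Its SD between denervated arrays was 0.03. Each of these arrays was set against the same control mean, so that SD leaves out the spread between controls. The difference over all tested probes was -0.42, -0.37 with quantile normalization and -0.26 with normexp background correction. A lower relative yield of the transcripts these IDs stand for may remain as a hypothesis, as may slide effects on probes of different design; naming the IDs would be the next step.

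The level of the control probes depended on the scaling. After scaling on the 75th percentile, the E1A level was 1.81 ± 0.34 (log2, SD, n = 4) on control and 1.18 ± 0.13 on denervated arrays, a difference of -0.63 that did not pass the threshold after adjustment (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0667). Of 10 E1A probes, the 8 well above background on every array were lower by -0.45 to -0.75 in limma, with adjustment over the control probes. Also lower were 17 DCP probes by -0.35 to -0.98, 2 ERCC probes by -0.41, ETG05_66023 by -0.66 and GE_BrightCorner by -0.36. Before scaling, E1A differed by -0.17 (SE 0.14, n = 4 each, exact permutation p = 0.314) and negative control probes differed by -0.01 between the groups (exact permutation p = 0.771).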
